A study of Mus musculus with 12 samples.

How the data were processed

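MAPR maps R-loops, the structures in which RNA pairs with 1 strand of DNA and displaces the other, by letting a catalytically mutated RNase H fused to micrococcal nuclease (RHΔ-MNase) bind in nuclei and cut the DNA around it. Nuclei treated with MNase alone serve as the control. The 12 libraries came from splenic B cells of C57BL/6J mice aged 10 weeks. Per the labels, 6 libraries carry the genotype Dfl and 6 the genotype CD19 DKO, which the series' design text describes as a Tet2/3 double knockout. Each genotype has 3 RHΔ-MNase and 3 MNase-only libraries, numbered 1 to 3 in the labels. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

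The values used are RPKM (reads per kilobase of region and per 1000000 reads of the library), which the authors deposited for 9722 regions and 12 libraries in 1 table. Per the submitters' processing notes, reads were aligned to mm10 (GRCm38) with Bowtie 1.1.2, and SAMtools was used. PCR duplicates were marked with Picard 2.7.1 and kept. Per the same notes, broad peaks were called with MACS2 in each sample against its control, and peaks shared between replicates were merged with HOMER. Per the deposited table, the regions are the union of G-quadruplex and R-loop peaks. The regions were therefore partly chosen as higher than the control in these libraries, so a higher RHΔ-MNase than MNase-only signal is partly built in. The program that made the RPKM values is not given in the sources used here. Regions ran from 124 to 13890 bp with a median of 749 bp, and 0 of them overlapped.

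The low RPKM values fell on the steps that whole reads give for the length of each region, which recovered the depth of each library. Of the values where rounding could hide less than 0.25 of a read, 99.97% to 100% lay within rounding plus 0.01 of a read of a whole number. With RHΔ-MNase the implied depths were 8640000, 11270000 and 15760000 reads for Dfl libraries 1, 2 and 3, and 7670000, 14990000 and 15650000 reads for the DKO libraries. With MNase alone they were 6600000, 19650000 and 17300000 reads for the Dfl libraries and 5950000, 12490000 and 10600000 reads for the DKO libraries. The median region held 21 to 113 reads in an RHΔ-MNase library and 4 to 16 reads in an MNase-only library, so single regions were measured with much less precision in the control. Reads that are PCR duplicates were kept and are not independent molecules.

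Regions were placed against the RefSeq gene spans of the same build, which came without strand, exons or sequence. A region was named for the protein-coding gene, or failing that any gene other than a pseudogene, whose span it overlapped most, and otherwise "near" the closest protein-coding span. The plan had been to name regions by the nearest transcript start, which the spans alone do not give. Regions within 1000 bp of either end of a protein-coding span formed the gene boundary class, other regions overlapping a span the gene interior class, and the rest the class outside genes. Promoter, exon and intron classes, GC content and G-quadruplex motifs were planned and not run, since they need transcript starts or sequence. A region belonged to a gene list when it lay within 1000 bp of or inside the span of a listed gene.

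Each comparison used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(RPKM + 0.5), two-sided, without a filter on low values. eBayes draws the spread of a region towards that of regions of like mean signal. For DKO against Dfl with RHΔ-MNase, and for the enzymes in Dfl, it did so almost fully, since p-values there came from a normal distribution. A region was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of regions with low RPKM. DKO was compared with Dfl within RHΔ-MNase and within MNase-only libraries, RHΔ-MNase was compared with MNase-only within each genotype, and the interaction was fitted on all 12 libraries. Values per library were compared with exact two-sided permutation tests, of which 11 form a family. With 3 against 3 libraries the smallest possible p is 0.1.

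Gene lists were tested with camera (preset correlation 0.01) where they had at least 3 regions. The 15 lists, fixed before the data were examined, covered AID targets and translocation partners, the immunoglobulin heavy chain constant genes, B cell identity, germinal centre and plasma cells, TET and DNA methylation, R-loop and G-quadruplex resolution, the DNA damage response, ribosomal proteins, replication-dependent histones, small nuclear and nucleolar RNAs with tRNAs, immediate early genes, T and NK cells, myeloid cells, erythroid and megakaryocyte cells, and housekeeping promoters. The patterns for the histone list also take in some histone genes that are replication-independent.

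The rule for named regions was fixed before the data were examined. It took up to 12 called regions in each direction with no overlap between the groups, by size of change. Where fewer than 5 passed in a direction, it took the 5 with the smallest unadjusted p. It also took up to 4 regions per list by smallest p, of which the text names and follows at most 2, a limit set after their values had been computed. It further took every region at Tet2, Tet3, Myc, Pim1, Pax5, Bcl6, Cd83 and the Igh constant locus (within 5000 bp), and the 5 regions with the highest mean RPKM per enzyme.

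The test was checked on simulated values with the real region levels and 200 changed regions among the 9722 of each comparison, under 3 models of the noise. Results below are for DKO against Dfl with RHΔ-MNase. With noise drawn independently from the unmoderated standard deviation of each region, which was the model used initially, limma recovered 1.49% of the 2-fold, 28.4% of the 4-fold and 71.2% of the 8-fold changes. The other models and the 8-fold changes were added after that model had recovered few changes. With the moderated standard deviation of each region, 5.97% of the 2-fold, 71.6% of the 4-fold and 98.5% of the 8-fold changes were recovered, and 3 unchanged regions were called. With the real deviations of the libraries moved to other regions, 0% of the 2-fold and 100% of the 4-fold and 8-fold changes were recovered. These deviations sum to 0 within each group, so each estimated change equalled the planted one (median error 0). Recovery under this last model therefore does not measure power. Between the models with drawn noise the recovery differed, and changes of 2-fold were mostly missed under both. For the interaction, 19.4%, 16.4% and 0% of the 4-fold changes were recovered under the same models in that order, the last with the same limit.

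The libraries of both enzymes with the same genotype and number share a name in the labels. Across regions, deviations from the group mean correlated between the enzymes at r = 0.27, 0.15 and 0.25 for Dfl 1, 2 and 3, all over 0.1, and at 0.22, 0.08 and 0.17 for DKO. The numbers therefore met the rule for pairing the enzymes in Dfl. In DKO the pair DKO 2 missed it, but the labels name each control for its sample and DKO 1 shared a shift of chromosome 5 between the enzymes, so pairing in DKO was left open. The alternatives were other pseudocounts, a filter on low values, quantile normalization, median centring, a replicate block, eBayes without trend or robust, each replicate left out, a fit on all 12 libraries, removal of the trend with region length (loess, span 0.5, without the planned GC term), subtraction of the MNase-only values and stricter thresholds. Alternatives chosen after seeing the data were limma voom on the recovered reads, array weights, regions or chromosomes left out, wider or narrower windows around listed genes, Dfl library 1 left out with median centring, and both RHΔ-MNase libraries numbered 1 left out. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.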

Results

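R-loop signal was measured by MAPR in 12 libraries of splenic B cells, with 3 RHΔ-MNase and 3 MNase-only libraries for each of the genotypes Dfl and DKO. The title of the series asks whether loss of TET enzymes, the dioxygenases that oxidise 5-methylcytosine, raises the levels of R-loops and G-quadruplexes in B cells. The RPKM values covered 9722 regions, of which 8296 overlapped an annotated gene and 7799 a protein-coding gene. Depth ran from 7670000 to 15760000 reads with RHΔ-MNase and from 5950000 to 19650000 reads with MNase alone.

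The targeted genes were examined before any comparison. Tet2 had 1 region at its boundary (mm10, chromosome 3, 133544276 to 133544673), where RHΔ-MNase gave 4.07, 8.70 and 12.12 RPKM in Dfl libraries 1, 2 and 3 and 7.21, 4.86 and 3.37 RPKM in DKO libraries 1, 2 and 3. Tet3 had 1 region at its boundary (chromosome 6, 83455090 to 83457359), with 2.14, 7.12 and 7.19 RPKM in the Dfl libraries and 5.29, 5.11 and 5.01 RPKM in the DKO libraries. The log2 fold change of DKO over Dfl was -0.58 at Tet2 (SE 0.52) and 0.07 at Tet3 (SE 0.50), and both had a limma adjusted p of 1.0. Over 22 alternatives the value at Tet2 ranged from -1.24 to -0.26 and passed in 3. At Tet3 it ranged from -0.46 to 0.33 and passed in 0. Whether either region lies in the deleted part is not given in the sources used here, so these values do not check the genotype labels.

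The comparison of RHΔ-MNase with MNase alone shows where the R-loop probe added signal over the nuclease. In Dfl cells 9480 of the 9722 regions were higher with RHΔ-MNase, 5 were lower and 237 were not called (limma, Benjamini-Hochberg adjusted p under 0.05), with a median fold of 4.46. With the Dfl libraries paired by number, 9534 were higher and 13 lower. In DKO cells 9535 were higher, 7 were lower and 180 were not called, with a median fold of 4.03. Both genotypes shared 9446 of the higher regions, against 9297.7 for independent lists of these sizes. The AID list, which holds genes that activation-induced deaminase is known to mutate or break, was higher at 33 of 33 regions in both genotypes, as were 23 of 23 regions of the B cell identity list. At a region of Pax5, the transcription factor that maintains B cell identity (chromosome 4, 44704413 to 44704836), RHΔ-MNase gave 11.7 ± 4.96 and MNase alone 1.23 ± 0.79 RPKM in Dfl cells (mean ± SD, n = 3). The region at Tet2 gave 8.30 ± 4.04 and 0.66 ± 0.09 RPKM in the same cells. Part of this difference is built in, since regions were chosen as peaks over the control in these libraries, and it was common to nearly all regions: after each library was centred on its median, 1 region was called higher and 48 lower in Dfl cells, and 12 higher and 70 lower in DKO cells.

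The few regions with less signal under RHΔ-MNase included 2700054A10Rik on chromosome 17 (13552838 to 13553077), which was lower in both genotypes, at 39.8 ± 21.5 against 94.0 ± 13.6 RPKM in Dfl cells and 26.5 ± 1.38 against 80.0 ± 24.4 RPKM in DKO cells (n = 3 each, limma adjusted p 0.038 and 0.0069). A neighbouring region of 2700054A10Rik was lower in DKO cells (log2 fold change -1.62). Cnga3, which encodes a subunit of the cone photoreceptor channel, was lower in Dfl cells (-1.57), as were regions near Gm3327 (-1.36), Pudp (-1.19) and Ndst3 (-0.65). Regions at Gm41427 (-1.13) and Ankrd13b (-0.81), near Arrdc4 (-1.53) and Btbd35f10 (-0.58), and on an unplaced scaffold (-0.96) were lower in DKO cells. The mitochondrial regions stood out by level: mt-Rnr2, CYTB, ND4 and ND2 had the highest mean RPKM with RHΔ-MNase, followed by a nuclear region near Gpd2, and mt-Rnr2, ND4, CYTB, ND2 and ND5 had the highest with MNase alone.

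The median RPKM over all regions, which asks whether R-loop signal differed as a whole, was 6.40 ± 2.98 in Dfl and 7.06 ± 0.70 in DKO libraries with RHΔ-MNase (mean ± SD, n = 3 each, exact two-sided permutation p 0.9, adjusted over 11 tests 0.9). With MNase alone it was 0.90 ± 0.20 and 1.32 ± 0.48 (n = 3 each, exact permutation p 0.3, adjusted 0.66). The ratio of the medians of both enzymes was 6.92 ± 2.44 in Dfl and 5.86 ± 2.15 in DKO (n = 3 each, exact permutation p 0.7, adjusted 0.856). None of the 11 differences in this family could reach 0.05, because the smallest p that 3 against 3 libraries allow is 0.1. Dfl library 1 lay apart, with a median of 3.08 RPKM against 7.29 and 8.84 in Dfl libraries 2 and 3. The DKO medians were 6.48, 7.85 and 6.86 RPKM, and without Dfl library 1 the DKO mean was lower than the Dfl mean by a difference of -1.003 RPKM (exact permutation p 0.3).

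The mean RPKM of the 8 mitochondrial regions also varied widely. With RHΔ-MNase it was 147, 27.7 and 27.3 in Dfl libraries 1, 2 and 3 and 203, 231 and 184 in the DKO libraries (exact permutation p 0.1, adjusted 0.55). With MNase alone it was 353, 6.25 and 11.1 in the Dfl libraries and 521, 96.6 and 136 in the DKO libraries (exact permutation p 0.5, adjusted 0.825). With both enzymes Dfl library 1 lay nearer the DKO mean than the other Dfl libraries did.

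**Figure D1:**
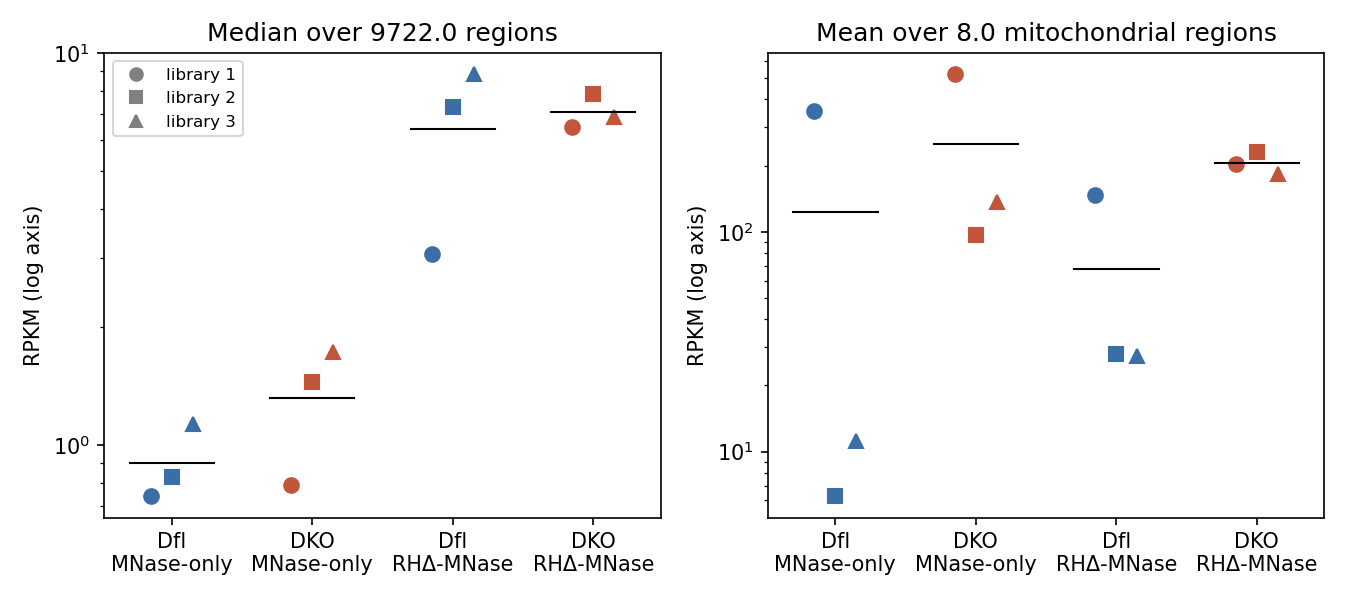
Median RPKM over all regions (left) and mean RPKM over 8 mitochondrial regions (right) on log axes, with 1 point per library, shapes for library numbers and a line at each group mean. Dfl library 1 has the lowest RHΔ-MNase median (3.08 RPKM), and its mitochondrial mean (147 RPKM) lies between those of the other Dfl libraries and of the DKO libraries.

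The comparison of DKO with Dfl cells within RHΔ-MNase asks where R-loop signal differed between the genotypes. It called 8 of 9722 regions higher in DKO and 0 lower (limma, adjusted p under 0.05), and 340 regions had an unadjusted p under 0.05. The SE and p of a region in this fit come from the spread of regions of like mean signal and hardly from its own values. They therefore do not measure the spread at that region, which the SDs show where they are printed. With all libraries the largest change was in a region outside genes, 76491 bp from Oat, the gene of ornithine aminotransferase (chromosome 7, 132480653 to 132480984), which rose from 0.86 ± 0.60 to 8.11 ± 6.01 RPKM (n = 3 each, log2 fold change 2.55, SE 0.44, limma adjusted p 4.4e-05). This rank rested in part on DKO library 1 (14.93 RPKM, against 3.62 and 5.77 in DKO libraries 2 and 3), without which the log2 fold change was 2.02 at Oat and 2.04 at Mmp2. Without Dfl library 1 it was 2.71 at both Oat and Sdc4. A region 792 bp outside Sdc4, which encodes the cell-surface proteoglycan syndecan-4 (chromosome 2, 164423092 to 164423455), rose from 1.66 ± 1.43 to 8.07 ± 1.71 RPKM (log2 fold change 2.21). A region in the interior of Eef2k, the kinase of translation elongation factor 2 (chromosome 7, 120865158 to 120865422), rose from 1.31 ± 0.86 to 7.30 ± 3.90 RPKM (log2 fold change 2.12), and it also overlaps Gm15774. The limma adjusted p was 0.0054 for both.

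The other 5 called regions rose by similar amounts. A region 8877 bp from Mmp2, a secreted matrix metalloproteinase (chromosome 8, 92817984 to 92818413), rose from 0.59 ± 0.31 to 3.99 ± 0.27 RPKM (log2 fold change 2.08, limma adjusted p 5.2e-04). A region 71971 bp from Aldh8a1, an aldehyde dehydrogenase (chromosome 10, 21468549 to 21468914), rose by a log2 fold change of 2.09 (limma adjusted p 0.0020). Regions in the long noncoding RNA gene Gm34346 (chromosome 10, 98877950 to 98878242), 78007 bp from Dnajc5b (chromosome 3, 19429782 to 19430584) and at the boundary of Ablim1, an actin-binding protein (chromosome 19, 57314457 to 57315102), rose by 2.06, 1.92 and 1.69 on the log2 scale (limma adjusted p 0.048, 0.038 and 0.048). Of the 8 regions 5 lay over 1000 bp outside protein-coding genes (Fisher's exact test against the other regions, p 0.0057, adjusted over 5 classes 0.028), and 6 with the bound at 500 bp (adjusted 0.0036). This test treats regions of the same libraries as independent, and it does not separate location from low signal or region length. Over all regions the classes differed little, with a median log2 fold change of 0.23 outside genes and 0.19 at gene boundaries, whose regions were longer (median 925 against 444 bp). The signal at gene boundaries minus that outside genes differed between DKO and Dfl by -0.064 on the log2 scale (n = 3 each, exact permutation p 0.6, adjusted 0.825). In the MNase-only libraries, where no region passed, 3 of the 8 were also higher in DKO at an unadjusted p under 0.05, near Sdc4 (log2 fold change 1.48), in Gm34346 (1.14) and at Ablim1 (0.83, limma adjusted p 0.565 each).

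**Figure D2:**
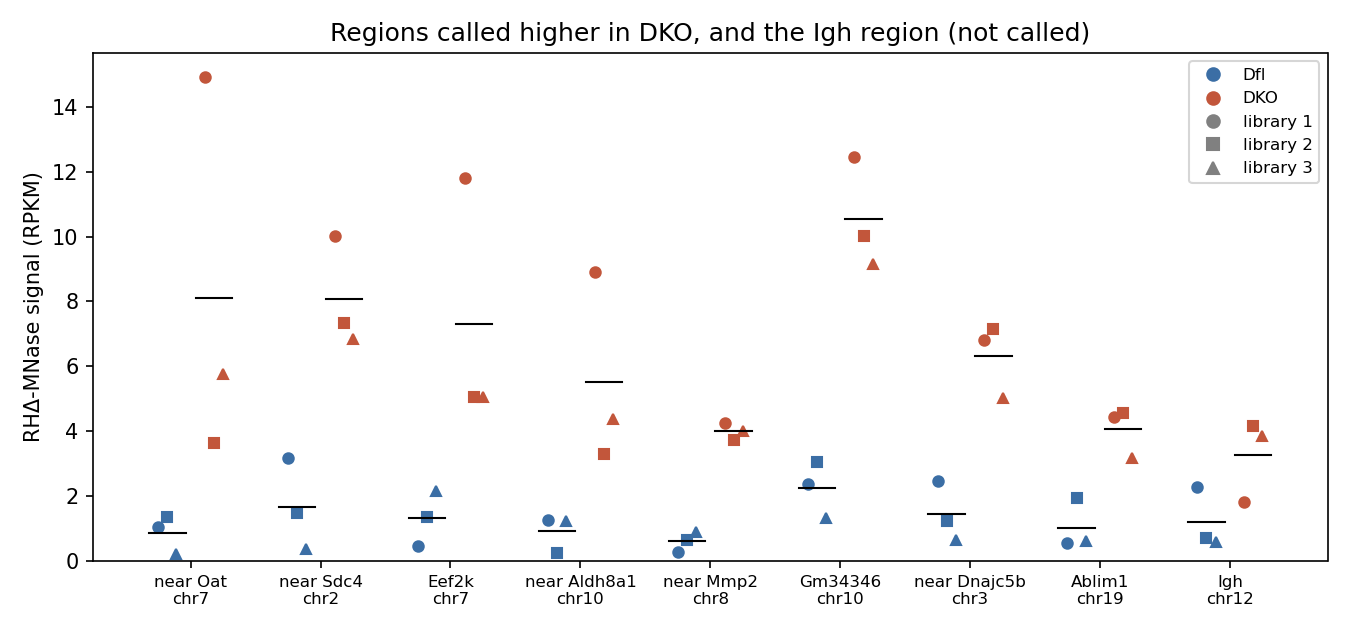
RPKM with RHΔ-MNase of the 8 regions called higher in DKO and of the region at the Igh constant locus, with 1 point per library, on a linear axis. At the 8 called regions all 3 DKO values lie above all 3 Dfl values.

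These regions were measured on few reads, with 1 to 17 reads per Dfl library and 14 to 86 per DKO library, and 7 of the 8 lay in the lowest quartile of mean RPKM. The call depended on the setting: 0 regions were called after quantile normalization, after median centring, and among regions above the 25th percentile of mean RPKM. The log2 fold changes of the 8 regions stayed positive in every alternative followed. The lowest was 1.02 at Ablim1, which no longer passed in 15 of 21 alternatives. With 1 library left out, 1 region (near Oat) was called without Dfl library 2, 5 without Dfl library 3, 2 without DKO library 1, and 4 each without DKO libraries 2 and 3, where the sets of 5 and of 4 held 1 lower region each. Across all regions the median log2 fold change was 0.19.

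Regions lower in DKO did not pass the test. The 5 with the smallest p lay near Myom2 (log2 fold change -1.18, limma adjusted p 0.187), near Acp7 (-1.08, adjusted p 0.299), at Gm41427 (-0.87, adjusted p 0.427), near Btbd35f10 (-0.72, adjusted p 0.730) and near Arrdc4 (-1.19, adjusted p 1.0). All 3 DKO values lay above all 3 Dfl values at 1049 regions and below them at 14. Chance alone gives 10% of regions over both directions and 486.1 each way, and both directions together held 1063. The value each way is no fair reference, because values were not centred and Dfl library 1 had the lowest median. That median was 3.08 RPKM, against 6.48 to 8.84 RPKM in the other RHΔ-MNase libraries. DKO values below all 3 Dfl values were thus unlikely from the start, and the uneven counts do not show a rise in DKO.

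Leaving out each library in turn was planned, and leaving out Dfl library 1, singled out after the values were seen, changed the count of called regions from 8 to 1176, with 320 higher and 856 lower. With the remaining libraries also centred on their medians, a setting added after the data were seen, 1033 were called, with 546 higher and 487 lower, and 781 were called with the same sign both ways. Mitochondrial regions led those that were higher, with CYTB at a log2 fold change of 3.38 and COX1 at 3.36 (limma adjusted p 4.1e-04 each). With MNase alone and all libraries, the log2 fold change was also high, at 2.64 for CYTB and 2.71 for COX1 (limma adjusted p 0.565 each). Regions that were lower included A530032D15Rik (-2.03), Atp8b3, a phospholipid-transporting ATPase (-1.95), and Megf11 (-1.69). They also included Sp110, a nuclear body protein of leukocytes (-1.61), and Nfe2l1, a transcription factor that controls proteasome genes (-1.58). These genes were chosen after their values were seen. With MNase alone and all libraries, DKO over Dfl was -0.34 at A530032D15Rik and -0.82 at Sp110. It was 0.72 at Atp8b3, 0.09 at Megf11 and -0.09 at Nfe2l1. The interaction called 0 regions with all libraries and 0 without Dfl RHΔ-MNase library 1. A change in R-loop signal beyond MNase alone was therefore not shown at the higher or lower regions named here. All 8 regions called with every library were also called without Dfl library 1, with and without centring. In the left-out library, 443 of the 546 higher and 379 of the 487 lower regions had a value nearer the DKO mean than the mean of Dfl libraries 2 and 3. These regions were selected for a difference between DKO and Dfl libraries 2 and 3, and the share over all regions was not computed. The counts alone therefore do not show that Dfl library 1 resembles DKO.

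Gene lists fixed before the data were examined were then compared, on log2 fold changes relative to the median of all regions. Of 13 lists tested with camera 0 shifted (adjusted p under 0.05), the smallest being the myeloid list (p 0.023, limma camera adjusted p 0.303), and 0 regions of any list were called over all regions. With an estimated correlation the adjusted p was 0.987 for every list. The AID list had a relative median of -0.10 over 33 regions. It held the only region of any list that passed when adjusted over the list alone, at Bach2, a transcriptional repressor that guides B cell differentiation (chromosome 4, 32257725 to 32258444), with 1.89 ± 0.47 RPKM in Dfl and 6.73 ± 1.29 RPKM in DKO (n = 3 each, log2 fold change 1.60, limma p 7.3e-04 and adjusted p over all regions 0.296). With MNase alone this region had 0.36 ± 0.24 and 1.16 ± 0.40 RPKM (n = 3 each, log2 fold change 0.94, limma adjusted p 0.565), and the interaction had a limma adjusted p of 1.0. For every other list the count adjusted over the list alone was 0.

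A further 5 lists had negative relative medians and did not pass. The B cell identity list had a relative median of -0.23 over 23 regions, with Pou2f2, an octamer-binding factor of B cells, at a log2 fold change of 1.04 and Cd79b, a signalling chain of the B cell receptor, at 1.06 (-0.28 without Dfl library 1). The germinal centre and plasma cell list had -0.17 over 8 regions (Prdm1, the regulator of plasma cell fate, 0.56 and Mzb1 -0.43). The TET and DNA methylation list had -0.12 over 7 regions, where Dnmt3a, a de novo DNA methyltransferase, had 0.47 (-0.27 without Dfl library 1). The DNA damage response list had -0.11 over 16 regions (Lig4, a ligase of end joining, 0.52 and a region shared by Brca1 and Nbr1 0.55). The immediate early list had -0.02 over 26 regions (Mcl1 0.85 and Nr4a1 0.62), and its median turned positive in 8 of 19 alternatives.

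Another 5 lists had positive relative medians, also without passing. The ribosomal protein list had a relative median of 0.16 over 67 regions (Rpl27 0.99 and Rpl27a 1.02), the histone list 0.15 over 23 regions (H2bc22 1.03 and H3f3b, which is replication-independent, 0.76), and the list of small nuclear and nucleolar RNAs with tRNAs 0.11 over 92 regions (Snord49a and Snord49b in 2410006H16Rik 1.39 and a tRNA gene in Fbxo31 1.35). The R-loop and G-quadruplex resolution list had 0.10 over 18 regions, with Ddx39b, an RNA helicase of messenger RNA export, at 1.09 and Dhx9, a helicase that unwinds RNA and DNA, at 0.86. The housekeeping list had a median of 0.02 over 11 regions but a mean of -0.09, with a test on the lower side (Rplp0 0.60 and a region shared by Sdha and Ccdc127 0.62). Without Dfl library 2 the relative medians of the histone, small RNA and housekeeping lists were negative (-0.093, -0.045 and -0.044). Without Dfl library 1 and with centring, the ribosomal protein and small RNA lists were higher (limma camera adjusted p 0.044 each), and with an estimated correlation their adjusted p was 0.479 and 0.377.

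Marker lists of other cell types were small. The myeloid list had -0.21 over 5 regions (Spi1, which B cells also express, -0.79 and Fcgr3 -0.57), and the erythroid and megakaryocyte list -0.36 over 4 regions (Itga2b -0.40 and Tfrc -0.21). Without Dfl library 1 the relative medians of these lists were -0.32 and -0.65 (limma camera adjusted p 0.055 each). Over 22 alternatives Spi1 ranged from -1.56 to -0.32 and Fcgr3 from -1.25 to -0.25, and each passed in 4. Itga2b ranged from -1.07 to -0.04 and passed in 3, and Tfrc ranged from -0.79 to 0.12 and passed in 2. The T and NK cell list had 2 regions (Cd5 0.77 and Lck -0.02) and the immunoglobulin heavy chain constant list 0 regions, so these 2 were not tested.

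Loci of interest in B cell lymphoma did not pass. Pim1, a kinase, had a log2 fold change of 0.52, the 3 regions of Pax5 had -0.03, -0.16 and -0.13, and the 2 regions of Cd83, an activation marker, had -0.12 and -0.20 (limma adjusted p 1.0 for each). Myc and Bcl6 had 0 regions within 1000 bp. A region of the Igh locus 1556 bp beyond the span of Ighm (chromosome 12, 113424286 to 113425299) had 1.18 ± 0.96 RPKM in Dfl and 3.26 ± 1.28 RPKM in DKO (n = 3 each, log2 fold change 1.24, SE 0.40, limma adjusted p 0.427). This region held 20, 8 and 9 reads in Dfl libraries 1, 2 and 3 and 14, 63 and 61 reads in the DKO libraries. DKO library 1 lay below Dfl library 1 at similar depth, so the groups overlapped. Without Dfl library 1, the library against the direction, and with centring the log2 fold change of the region was 1.85 (limma adjusted p 0.017). The MNase-only values were also higher in DKO, at 0.46 ± 0.25 and 1.35 ± 0.47 RPKM (n = 3 each, log2 fold change 0.94, limma adjusted p 0.565), and the interaction log2 value was 0.30 (limma adjusted p 1.0), so a change in R-loop signal was not shown.

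The same comparison within the MNase-only libraries measures differences without the R-loop probe. limma called 0 of 9722 regions, and 854 had an unadjusted p under 0.05, with a median log2 fold change of 0.33. At the region near Oat the MNase-only values were 0.82 ± 0.61 RPKM in Dfl and 0.25 ± 0.26 RPKM in DKO, and at Sdc4 0.53 ± 0.28 and 2.41 ± 1.05 RPKM (n = 3 each). After median centring limma called 1 region, lower at Nr2e3, a nuclear receptor of photoreceptors (log2 fold change -2.16, adjusted p 0.038).

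The genotype by enzyme interaction asks whether the genotypes differed more with RHΔ-MNase than with MNase alone. limma called 0 of 9722 regions, and 121 had an unadjusted p under 0.05. The smallest adjusted p was 0.095, at the region near Oat, where the difference of differences was 3.30 on the log2 scale. This region was called when the enzymes were paired by number within each genotype (limma adjusted p 6.2e-06). It was also called with a pseudocount of 1 (limma adjusted p 0.012) and when Dfl RHΔ-MNase library 2 (0.037), DKO RHΔ-MNase library 2 (0.0090) or 3 (0.034), Dfl MNase-only library 3 (0.0087) or DKO MNase-only library 1 (0.047) was left out. The other 7 called regions had interaction adjusted p of 1.0, so a difference from MNase alone was not shown for them.

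Signal and region length were related in every library. The Spearman rho of RHΔ-MNase signal with length across regions, which are not independent replicates, was -0.417 ± 0.022 in Dfl and -0.577 ± 0.055 in DKO libraries (n = 3 each, exact permutation p 0.1, adjusted 0.55). The log2 ratio of DKO over Dfl was negatively related to length in 9 of 9 pairs of RHΔ-MNase libraries, with rho from -0.314 to -0.099, against -0.103 to 0.153 in pairs of the same genotype. With MNase alone it was negative in 6 of 9 pairs, with rho from -0.136 to 0.126, against -0.190 to 0.026 in pairs of the same genotype.

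The share of reads per chromosome differed in some library pairs. Chromosome 5 of the pair DKO 1 had 1.42 times its usual share with RHΔ-MNase and 1.46 times with MNase alone. In the pair Dfl 3 the log2 shifts with both enzymes were 0.30 and 0.30 on chromosome 16, 0.23 and 0.25 on chromosome 3, and 0.18 and 0.25 on chromosome 13, and in the pair Dfl 2 they were 0.17 and 0.20 on chromosome 16. These were 5 of 120 pairs of chromosome and name above 0.15 with both enzymes, and the remaining autosomes had an SD of 0.038 with RHΔ-MNase and 0.039 with MNase alone. Below -0.15 lay 0 pairs with both enzymes, 1 with RHΔ-MNase only (chromosome 6 of Dfl 3, -0.17 against -0.03) and 2 with MNase alone only. The latter were chromosome X of Dfl 2 (-0.34 against 0.02) and of Dfl 3 (-0.27 against -0.14).

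**Figure D3:**
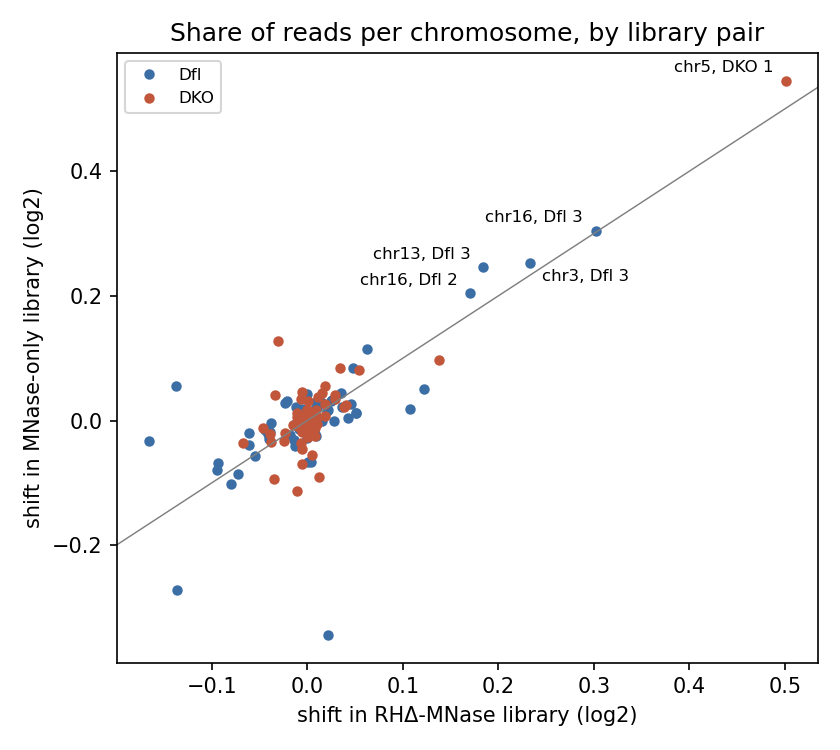
Log2 shift of the share of reads per chromosome with RHΔ-MNase (horizontal) and with MNase alone (vertical), with 1 point per chromosome and library pair and a line at equal values. The 5 labelled points lie above 0.15 with both enzymes, with chromosome 5 of DKO 1 farthest out at 0.50 and 0.55.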

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

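Among the tests here, those of depth and of targeting efficiency for Dfl library 1, and those of a single library preparation (both) and of a gain of copies for the chromosome shifts, were chosen after the result was seen.

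A region near Btbd35f10 (chromosome X, 3769683 to 3770043) drew attention because RHΔ-MNase gave more signal than MNase alone in all 3 Dfl pairs and less in all 3 DKO pairs. The difference of differences was -0.82 on the log2 scale. The interaction test did not pass (limma adjusted p 1.0), and no value at the region exceeded 0.64 RPKM.

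Dfl RHΔ-MNase library 1 stood apart from Dfl libraries 2 and 3, and the count of regions called between the genotypes rested on it. Lower depth is argued against for its low median RPKM only, since DKO library 1 had fewer reads and a median 2.10 times as high. RPKM is already scaled to depth, so this outcome was likely from the start. Whether depth affected the profile of Dfl library 1 across regions was not tested. Less efficient targeting with an otherwise typical Dfl profile is argued against by its correlation across regions. This was higher with the DKO libraries (mean rho 0.725) than with Dfl libraries 2 and 3 (0.549), a difference of -0.18. That test does not cover less efficient targeting that leaves more MNase background in the profile. The ratio of the medians of both enzymes was 4.16 in Dfl 1 and 8.78 and 7.82 in Dfl 2 and 3. In DKO 1, 2 and 3 it was 8.20, 5.41 and 3.97. Comparisons that share no library correlated with a mean r of 0.568. Any cause that makes Dfl libraries 2 and 3 alike and Dfl library 1 nearer the DKO libraries gives this, so it does not single out preparation. A difference in preparation that sets Dfl libraries 2 and 3 apart from the rest stays open. A wrong label on the Dfl 1 libraries stays open too, although the rho of signal and length in Dfl 1 (-0.438) lay nearer those of Dfl 2 and 3 (-0.420 and -0.394) than those of the DKO libraries (-0.526 to -0.635) and its median RPKM was below all others, and a biological difference was not tested.

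The ratio of DKO over Dfl signal decreased with region length (rho -0.297). Noise of short regions is argued against by a rho of -0.232 (bootstrap SE over regions 0.013) among the 6576 regions with at least 50 reads on average. The preparation difference around Dfl library 1 is argued against as well, since Dfl library 1 over Dfl libraries 2 and 3 had a rho of 0.043 (SE 0.011). The SEs given here resample regions and leave out the larger spread between libraries. Pairs of the same genotype ran from -0.103 to 0.153 with RHΔ-MNase and from -0.190 to 0.026 with MNase alone. A difference in MNase digestion cannot be told apart, because the MNase-only ratio had a rho of -0.043 (SE 0.010), closer to the bound of -0.05 than its spread (a rule added after the value was seen), with DKO 1 positive in all 3 MNase-only pairs (0.055 to 0.126) despite the most negative RHΔ-MNase pair (-0.314) and DKO 2 and 3 negative in all 6 (-0.136 to -0.048). The genotype could also underlie the trend, and GC content was not tested because no sequence was used here.

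Whole chromosomes were shifted upwards in some pairs of libraries, such as chromosome 5 in DKO 1, and chromosome 16 in both Dfl 2 and Dfl 3. An effect of a single library preparation is argued against by a mean shift of 0.311 in the MNase-only libraries of all 5 pairs above 0.15 with RHΔ-MNase, chosen without regard to MNase alone (0.337 for the 4 largest). For these 4, which leave out chromosome 16 of Dfl 2, a single segment is argued against by 97.2% of 106 bins of 10 Mb lying above 0. Each bin was counted once per enzyme. The bins below 0 lay on chromosome 3 of Dfl 3 with RHΔ-MNase. There 13 of 16 bins were above 0 and the lowest was at -0.38, against 16 of 16 above 0 with MNase alone. The mean absolute difference between the enzymes at the 4 was 0.032 for a mean RHΔ-MNase shift of 0.305, which is consistent with a gain of chromosome copies in part of the cells. That remains a hypothesis, since both libraries of a name may share cells or other handling, no karyotype was used here, and no pair lay below -0.15 with both enzymes. The Dfl shifts also partly recurred in Dfl 2 and Dfl 3, the pairs that a preparation difference may set apart. With RHΔ-MNase, chromosome 7 was at 0.11 and 0.12 and chromosome 6 at -0.14 and -0.17 in Dfl 2 and 3. Chromosomes 3 (-0.08 and 0.23) and 13 (-0.09 and 0.18) went opposite ways.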

How the results depend on the processing

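Array weights, voom, regions or chromosomes left out, other windows around listed genes, and Dfl library 1 left out with centring or together with DKO library 1 were chosen after the data were seen. Of 1403 values under alternatives, the main results kept their side and size in 87, moved in 32 and reversed in 1. Single regions and list medians kept theirs in 1088, passed newly in 77, no longer passed in 70 and reversed in 48. Single regions covered those of the naming rule, with the 2 of smallest p per list. Where values moved the cause was not tested, except where stated. For DKO against Dfl with RHΔ-MNase, 8 regions were called in the main setting. The count was 0 above the 25th percentile of mean RPKM, where 7 of the 8 were not tested, 0 after quantile normalization and 0 after median centring. It was 15 without the trend, 2 in a fit on all 12 libraries, 5 with the length trend removed, 1 with MNase-only RPKM subtracted and 5 at adjusted p under 0.01. It was 1063 by non-overlap of the values (chance share 10%), 2477 with array weights (926 higher, 1551 lower), 1033 without Dfl library 1 with centring and 1773 without both libraries numbered 1 (597 higher, 1176 lower). Leaving out 1 library gave 1 to 1176, the highest without Dfl library 1. With the replicate block it was 32 (28 higher, 4 lower). Same-numbered Dfl and DKO libraries correlated at r = -0.08, -0.12 and -0.02 with RHΔ-MNase, and 0 of 3 numbers matched best. The numbers thus did not meet the rule for pairing the genotypes, but these correlations cannot exclude a batch shared by number. With MNase alone, the libraries numbered 1 had the fewest reads and the highest mitochondrial means of their genotype (353 RPKM in Dfl and 521 RPKM in DKO). The block also gave 1 call in the interaction (near Oat), 9547 for RHΔ-MNase over MNase-only in Dfl (13 lower) and 9568 in DKO (10 lower). With voom on the recovered reads 12 regions were called, all higher.

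MNase-only calls moved to 1 with median centring. RHΔ-MNase over MNase-only calls moved to 40 with quantile normalization and 49 with median centring in Dfl, and to 67 and 82 in DKO, since both settings remove a difference common to all regions by construction. Leaving out 1 library gave 9081 to 9565 in Dfl and 9407 to 9570 in DKO. The interaction moved to 1 with a pseudocount of 1 and ranged from 0 to 1 with 1 library left out. Gene list shifts moved to 2 without Dfl library 1 with centring, and were 0 when the correlation was also estimated. The difference in median RPKM of DKO and Dfl, 0.66 with all libraries, ranged from -1.003 to 1.88 with 1 library left out.

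The directions that reversed belonged to values that did not pass in the main setting. The immediate early list median was 0.0066 with quantile normalization, 0.013 with the window of 2 kb, 0.063 without Dfl library 1 with centring (0.063 with an estimated correlation) and 0.15 above the 25th percentile. With MNase-only RPKM subtracted the region near Arrdc4 was at 0.028. With quantile normalization Tet3 was at -0.13, and with median centring at -0.17. With array weights Cd79b was at -0.25, Lck at 0.071 and Tet3 at -0.43. Without Dfl library 1 with centring Cd79b was at -0.10, Dnmt3a at -0.088 and Tet3 at -0.26, and without both libraries numbered 1 Cd79b was at -0.41, Lck at 0.11 and Tet3 at -0.46. With the length trend removed, with or without the replicate block, Lck was at 0.19 and the Cd83 region at 43787598 at 0.0058. With 1 library left out, list medians ranged from -0.093 to 0.34 (histone), -0.045 to 0.14 (small RNA), -0.089 to 0.063 (immediate early) and -0.045 to 0.14 (housekeeping). Regions ranged from -0.28 to 1.80 (Cd79b), -1.24 to 0.055 (Mzb1), -0.27 to 0.99 (Dnmt3a), -0.28 to 0.37 (Lck), -0.79 to 0.12 (Tfrc), -0.44 to 0.33 (Tet3), -0.56 to 0.39, -0.57 to 0.045 and -0.72 to 0.25 (Pax5 at 44671092, 44704413 and 44672493), and -0.47 to 0.25 and -0.72 to 0.23 (Cd83 at 43787598 and 43784300). Depth limits the called regions, where single Dfl libraries held as few as 1 read. Not run were a GC correction and classes by exon, GC content or G-quadruplex motif, which need a genome, count tests other than voom, a design without replicates, which did not apply, and the robust setting for gene lists, which camera does not offer.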

Other observations

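The tests by splits of the libraries were planned, and the descriptions of nuclear regions that follow the mitochondrial ones and of length classes were added after the data were seen.

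Besides the 8 mitochondrial regions, 6 nuclear regions followed the mitochondrial signal, of which 3 lay near Col19a1 and 1 each near Galc, Myo3a and Nxph1. These 6 regions were chosen by their close correlation with the mitochondrial mean across the MNase-only libraries. Their MNase-only values therefore follow it by construction. Their mean RPKM with RHΔ-MNase was 65.7, 12.8 and 13.8 in Dfl libraries 1, 2 and 3 and 101, 104 and 85.0 in the DKO libraries, and with MNase alone 163, 2.79 and 5 in the Dfl libraries and 237, 41.0 and 56.7 in the DKO libraries. With regions sorted by length, the relative log2 ratio of DKO over Dfl had a median of 0.16 in the shortest class, then 0.07 and -0.01, and -0.14 in the longest.

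The libraries of each comparison can be divided into 10 splits of 3 and 3, which are too few for a share under 0.05. For DKO against Dfl with RHΔ-MNase, 2 of the 10 splits gave at least as many calls, with 8 in the real split and 13 in the highest other, which set Dfl 1 with DKO 2 and DKO 3. For MNase alone 10 of 10 gave at least as many, with 0 real and 0 in the highest other. RHΔ-MNase against MNase alone had 9485 real calls and 7 in the highest other in Dfl, and 9542 and 0 in DKO, so 1 split each, the real one, reached that count. The interaction had 0 real calls and 1 in the highest other, and the gene lists 0 and 3, so 10 of 10 splits reached the real count for both.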
